A study of Mus musculus with 12 samples.

How the data were processed

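The series holds 12 RNA-seq libraries of mouse primary neural stem cells in 4 groups of 3: wild type and Chd5-/-, each taken 3 h and 48 h after the start of differentiation. Per the labels, the cells were kept in medium with epidermal growth factor and fibroblast growth factor 2, and differentiation was started by replacing it with neurobasal medium containing B-27. RNA was extracted with Trizol and libraries were made with the TruSeq Stranded mRNA kit, per the labels. The labels name no separate animals, cultures or lines behind the replicate numbers, so the p-values given here measure only the spread between these samples. The labels also do not say which part of Chd5 was deleted.

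Each library has 1 deposited table of transcripts made with Salmon, per the submitters' processing notes. Per the file headers, the tables hold estimated read counts (NumReads) and TPM, transcript abundances scaled to a fixed total per library, for 140658 transcripts. The Salmon version, its settings, and the transcript set behind its index are not given in the sources used here. Transcript names were matched to the GENCODE M21 annotation of the mouse genome build GRCm38, a copy that need not be the one behind the index. Of the transcripts, 140137 matched and 521 did not. The 521 held between 0.135% and 0.181% of the reads of a library and were left out. With the version of the name included, 139921 matched, and the length in the tables equalled that in the annotation for 139921 of them. The deposited estimated counts were summed over the transcripts of each of 54356 genes and rounded to whole numbers. TPM values were used for Chd5 alone.

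The libraries held between 14.11 and 18.71 M estimated reads. A gene with 0 reads in all 3 libraries of a group was given a floor of 3 counts over the group, and its fold change is given as a bound against that floor. Where a group had 1 to 3 counts, its level was taken as those counts over its summed TMM-scaled library size. The mean CPM of the higher group is given as a ratio to that level, with the 95% exact Poisson interval of the counts. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

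Counts were tested in edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 16043 genes. Libraries were scaled with TMM factors, and a quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries. The 5 contrasts were tested with two-sided quasi-likelihood F tests: Chd5-/- against wild type at 3 h and at 48 h, 48 h against 3 h within each genotype, and the genotype by time interaction. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of the contrast. Fold changes are on the log2 scale with their standard error (SE). Levels are CPM, counts per M reads of TMM-scaled library size, as mean and standard deviation (SD) of the 3 libraries of a group.

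The following choices were made before the data were examined: the model, the tests, most alternatives, 34 gene lists, and the rule for named genes. Genes were eligible to be named if they were among the 10 higher and 10 lower genes with the largest fold change of a genotype contrast that passed, reached a mean of 5 CPM in the higher group, and had all 3 libraries of 1 group above all 3 of the other. For the time contrasts the rule took 8 and 8, and for the interaction 5 and 5 without the demand on separation. Placeholder symbols, pseudogenes and sex-linked genes were left out of that rule. Up to 4 members of each list with the smallest p were eligible as well, and the sex-linked genes Xist and Kdm5d. From these, list members whose call held in every fit with 1 library left out were preferred as examples, a preference set after the values were seen. Cdkn2a, Pcdhgb7, Pcdhga6 and the 5 genes named from a second list of p53 targets fall outside the rule and were chosen after their values were seen.

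The gene lists covered neural stem cells and neural lineages, the cell cycle, p53 targets, ribosomes, chromatin regulators, regional transcription factors, signalling pathways, metabolic and stress responses, imprinted and sex-linked genes, mitochondrial mRNAs, and markers of other cell types. Each was tested against all other genes with camera in edgeR at a preset correlation of 0.01, adjusted over the 34 lists of a contrast, and again with an estimated correlation. The fry test in edgeR was run as an alternative. Counts of members that passed are given over all genes tested and adjusted over the list alone.

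The alternatives chosen before the data were examined were RLE size factors, no filter beyond 1 read, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), an offset for effective transcript length, only the libraries of the groups compared, replicate blocks, and each of the 12 libraries left out in turn. Omitting the 3 libraries that stood apart and a replicate block within the 48 h libraries were added after the data were seen.

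Whether equal replicate numbers pair libraries was checked across 14124 genes of at least 1 CPM, by the correlation of deviations from the group mean. Libraries of equal number correlated across genotypes at 3 h (r = 0.287, 0.146 and 0.143 for numbers 1, 2 and 3) and at 48 h (r = 0.73, 0.8 and 0.73), all above the preset 0.1. At each time 1 number carried this: at 48 h numbers 1 and 3 correlated crosswise as strongly (r up to 0.742), and at 3 h numbers 2 and 3 did (r up to 0.153). Genes are not independent, so these values carry no p. Between times equal numbers did not correlate (r from -0.018 to 0.02), so no such pairing was assumed. A replicate-number block shared by both times ignored this (907 genotype calls at 3 h, 408 at 48 h, no camera call changed). A block within 48 h gave 1330.

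The model was tested on simulated data with the depths of these libraries, the spread fitted to each gene, and 200 changed genes at 3 h. The changed genes were drawn from the better expressed genes. Counts were drawn for each gene on its own, so no simulated library was shifted as a whole and genes did not move together. The shares that follow thus need not hold for the real libraries. With all 12 libraries it recovered 0% of genes changed 2-fold, 48% of those changed 4-fold, 90% of those changed 16-fold and 96% of those changed 64-fold, and 5.6% of its calls were unchanged genes. With the 3 libraries that stood apart left out it recovered 100% at each size, with 6.5% of calls on unchanged genes. Where no change was simulated, at 48 h, it made 0 calls with all libraries and 2 without the 3. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The deposited TPM of other genes and transcript-level tests were not used.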

Results

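RNA of mouse primary neural stem cells was sequenced in 12 libraries, 3 in each of 4 groups: wild type and Chd5-/-, 3 h and 48 h after growth factor medium was replaced by differentiation medium. The series asks which genes differ in Chd5-deficient cells during neuronal differentiation. At 3 h, the wild-type libraries held 14.11, 17.33 and 17.71 M estimated reads (replicates 1, 2 and 3) and the libraries labelled Chd5-/- held 18.71, 16.49 and 18.33 M. At 48 h, the wild-type libraries held 14.48, 16.11 and 15.68 M and the others 14.42, 14.48 and 14.12 M.

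In each group but the Chd5-/- group at 3 h, 1 library stood apart from the other 2. Wild-type replicate 1 at 3 h gave 13.75% of its reads to ribosomal protein genes, against 3.87% and 3.74% in replicates 2 and 3. Its reads lay on shorter transcripts, with a read-weighted mean length of 1805 bases against 3049 and 3077, and mitochondrial genes took 0.53% of its reads against 2.17% and 2.29%. At 48 h, replicate 2 of both genotypes kept high levels of cell cycle genes. The mean log2(CPM + 1) of the 20 mitosis genes was 7.13 in wild-type replicate 2 and 6.99 in replicate 2 labelled Chd5-/-, against 3.31 to 3.35 in the other 48 h libraries. All other pairs within a group lay far closer together, with a chi-square per gene between 1.82 and 5.99 where counting alone gives about 1. For the 3 libraries, that value against the others of their group lay between 156 and 514. Counts of called genes are given with all 12 libraries, and beside them without these 3, a choice made after the data were seen.

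Chd5 itself (ENSMUSG00000005045, chromosome 4, 152338651 to 152390194, GRCm38), which encodes a chromodomain helicase, was not lower in the libraries labelled Chd5-/- at 3 h. It had between 35 and 124 estimated reads per library. At 3 h it stood at 3.55, 3.93 and 4.66 CPM in wild type and at 5.25, 6.31 and 7.06 CPM in the libraries labelled Chd5-/- (log2 fold change 0.61 ± 0.31 SE, n = 3 per group, edgeR adjusted p = 0.257). At 48 h it stood at 6.6, 7.15 and 5.28 CPM in wild type and at 5.7, 3.34 and 2.97 CPM in the libraries labelled Chd5-/- (-0.66 ± 0.31, adjusted p = 0.467). With an offset for transcript length both directions turned, to -0.25 and 2.44, and neither passed (adjusted p = 0.884 and 0.289; over all alternatives 0.0679 to 0.884 at 3 h and 0.143 to 0.933 at 48 h). At 3 h all 3 libraries labelled Chd5-/- lay above all 3 of wild type, the opposite of a loss, and at 48 h the groups overlapped. Each 48 h library labelled Chd5-/- lay below the wild-type library of its number, and with a replicate block within 48 h the difference was -0.71 (adjusted p = 0.143). TPM gave another order. At 3 h it was 0.62, 0.26 and 1.84 in wild type and 0.34, 0.41 and 2.67 in the libraries labelled Chd5-/-, and at 48 h 0.62, 0.5 and 0.52 against 2.56, 3.88 and 2.6. It exceeded 1 only in the 5 libraries with 1.6 to 2.8 reads on Chd5-204, a transcript of 280 bases, so it rests on few reads. By counts or TPM, the level of Chd5 does not show a loss, and "labelled Chd5-/-" refers to the deposited genotype throughout. Chd5-202, a coding transcript of 9486 bases, had between 22.9 and 86.4 estimated reads in 5 of the 6 libraries labelled Chd5-/- and 0 in the remaining 1 and in all 6 wild-type libraries. The coding transcript Chd5-205 had 54.5, 55.9 and 72.2 reads in 3 wild-type libraries and 29.2 in 1 library labelled Chd5-/-. Most reads lay on the coding transcript Chd5-201 in 1 library labelled Chd5-/- at 3 h (98.7) and in 2 wild-type libraries at 48 h (106 and 53.3), so transcript use did not follow the label throughout. The labels do not give the deleted part, so no transcript could be checked against it.

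**Figure D1:**
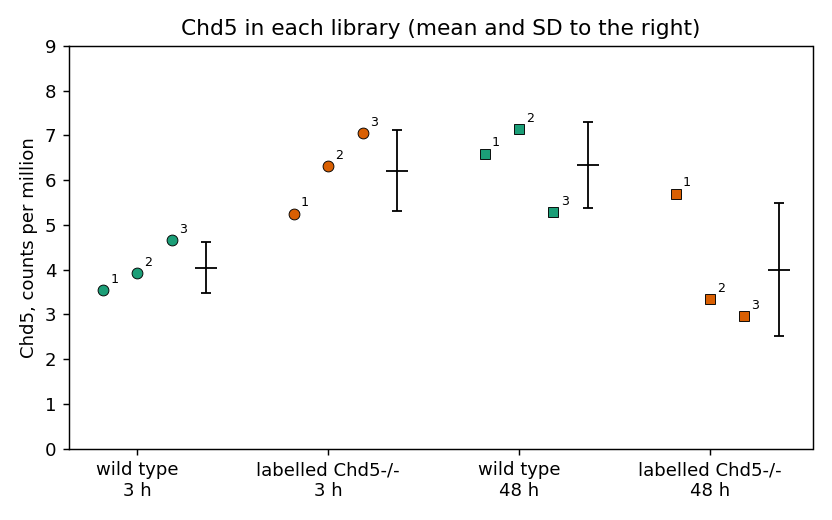
Chd5 in CPM (vertical axis) in each of the 12 libraries, by genotype label and time; numbers give the replicate, and the bar to the right of each group is the mean with SD. At 3 h the 3 libraries labelled Chd5-/- lie between 5.25 and 7.06, above the wild-type libraries.

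At 3 h after the medium change, the libraries labelled Chd5-/- carried more RNA of p53 target genes than wild type. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), encodes the cell cycle inhibitor p21. It stood at 49.2 ± 10.9 CPM in wild type and 695 ± 11.8 CPM in the libraries labelled Chd5-/- (mean ± SD, n = 3; log2 fold change 3.82 ± 0.29 SE, adjusted p = 6.37e-05). Genes of regional and lineage identity differed as well. Nkx2-2, a transcription factor of ventral progenitors and oligodendrocytes, was found only in the libraries labelled Chd5-/-, and Six3, a transcription factor of the forebrain, was lower in them. Genes of DNA replication and mitosis did not pass with all 12 libraries, while without the 3 that stood apart some of both passed, with medians of -0.13 and 0.08.

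Of 16043 genes tested, 1077 passed, 519 higher and 558 lower in the libraries labelled Chd5-/-, and 1015 of them changed at least 2-fold. Without the 3 libraries that stood apart, 8659 passed (4491 higher and 4168 lower), among them 1076 of the 1077 in the same direction. Among the genes higher in the libraries labelled Chd5-/-, Ddit4l (ENSMUSG00000046818, chromosome 3, 137621612 to 137628333), an inhibitor of mTOR signalling, stood at 306 ± 2.41 CPM against 1 read in all of wild type, a ratio of 13900 (95% counting interval 2500 to 550000). Nkx2-2 (ENSMUSG00000027434, chromosome 2, 147177546 to 147194243) had 0 reads in wild type and 32.8 ± 2.35 CPM, at least 496-fold higher. Abracl was at least 183-fold higher, and the ratios of Shisa6, Sostdc1, Rimbp2 and Itpripl2 were 1920, 1510, 654 and 171 (intervals 345 to 76000, 271 to 59600, 181 to 5400 and 58.4 to 828). Ank3, which encodes the axon initial segment scaffold ankyrin-G, rose from 0.254 ± 0.118 to 96.8 ± 5.55 CPM, and the Wnt receptor gene Fzd10 from 0.229 ± 0.155 to 47.4 ± 2.62 CPM. Smim20 rose by 7.87 ± 0.54 on the log2 scale.

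Among the genes lower in the libraries labelled Chd5-/-, Edil3 (ENSMUSG00000034488, chromosome 13, 88821472 to 89323223), which encodes an extracellular matrix protein, had 25.4 ± 17.3 CPM in wild type and 0 reads in the other 3 libraries, at least 434-fold lower. The matrix protein gene Mfap4 was at least 91.5-fold lower. Gap43, which encodes a growth cone protein, fell from 64.9 ± 8.13 to 0.337 ± 0.167 CPM. The actin-binding Tagln2 fell from 101 ± 57.5 to 0.196 ± 0.121 CPM and the lysosomal protease gene Ctsz from 71.6 ± 58.3 to 0.657 ± 0.141 CPM. Zcchc12 fell from 72.5 ± 28.1 to 0.177 ± 0.115 CPM. The histone deacetylase gene Hdac11 had 3 reads in the libraries labelled Chd5-/-, a wild-type excess of 420-fold (interval 144 to 2030). The excess was 502, 390 and 148 for Pitpnm1, Fgl2 and Mpg (intervals 90.1 to 19800, 70 to 15400 and 40.9 to 1220).

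Of the 17 measured genes of the list of Cdkn2a and p53 targets, 11 rose, 1 fell and 5 did not pass (12 rose and 1 fell adjusted over the list alone; median log2 fold change 2.22). Camera gave the list an adjusted p of 6.94e-12, and adjusted p = 0.0016 with an estimated correlation. Beside Cdkn1a, Ccng1 rose from 16.1 ± 6.36 to 314 ± 7.15 CPM, Eda2r from 6.06 ± 4.11 to 106 ± 5.42 CPM and Zmat3 from 22.5 ± 7.31 to 119 ± 8.23 CPM. The member that fell was Cdkn2a, whose products include the p53 activator p19Arf. It fell by 3.12 ± 0.59 on the log2 scale (adjusted p = 0.0108). It had 618 CPM in wild-type replicate 1, 139 and 141 CPM in replicates 2 and 3, and between 32.7 and 37.8 CPM in the libraries labelled Chd5-/-. Its call was lost without replicate 1, 2 or 3 labelled Chd5-/- at 3 h (adjusted p up to 0.064, and from 3.77e-12 to 0.064 over all alternatives). With the 3 libraries that stood apart left out, 13 members of the list rose and 3 fell.

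**Figure D2:**
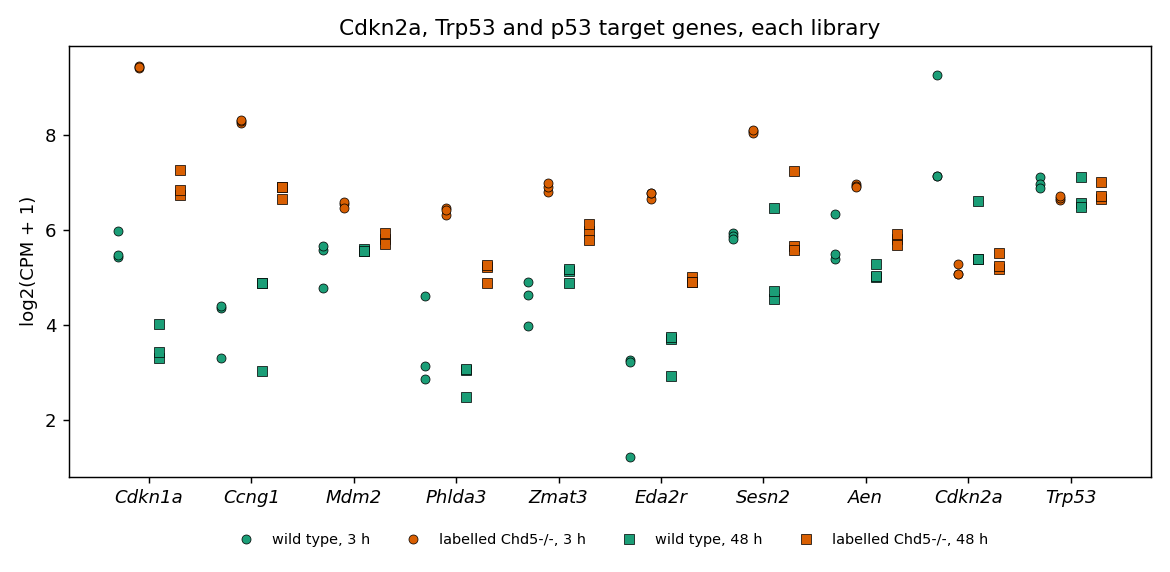
Level of Cdkn2a, Trp53 and 8 p53 target genes in each library, as log2(CPM + 1) (vertical axis); circles are 3 h, squares 48 h, green wild type and orange labelled Chd5-/-. At 3 h the libraries labelled Chd5-/- lie above wild type for the 8 targets and below it for Cdkn2a.

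The 63 ribosomal protein genes were lower as a set (median -1.43, camera adjusted p = 8.5e-07; adjusted p = 0.897 with an estimated correlation). Singly, 0 passed in edgeR and limma-voom, 43 reached an unadjusted p under 0.05 in edgeR, and DESeq2, which gave p-values for 30 of them, called 1. This set moved with wild-type replicate 1, in which its mean log2(CPM + 1) was 10.97 against 8.61 and 8.54 in replicates 2 and 3, and without the 3 libraries its median was -0.04 (6 rose and 15 fell; camera adjusted p = 0.514). Of 10 midbrain and hindbrain transcription factors, 2 rose (4 adjusted over the list alone): Irx1 from 0.0745 ± 0.0846 to 6.52 ± 0.741 CPM and En2 from 3.24 ± 0.979 to 18.4 ± 1.42 CPM. Camera gave that list an adjusted p of 0.0117, and adjusted p = 0.897 with an estimated correlation. Of 14 forebrain factors, 2 rose and 3 fell (6 and 3 adjusted over the list alone). Six3 fell from 51.3 ± 5.57 to 6 ± 1.34 CPM. Of 10 Hox genes 1 rose, Hoxa5, from 12.3 ± 0.881 to 32.2 ± 0.0568 CPM (2 adjusted over the list alone; median 1.06, and 0.74 with the member at 0 reads at its bound).

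Among lineage markers, members moved both ways and no list passed camera with all 12 libraries. In the other 9, astrocyte markers passed as lower (6 rose and 9 fell; camera adjusted p = 0.000712, and adjusted p = 0.079 with an estimated correlation). Fibroblast and smooth muscle markers passed there too (5 rose and 6 fell; median -0.88, while the test pointed up; camera adjusted p = 0.0214, and adjusted p = 0.333 with an estimated correlation). In the oligodendrocyte lineage list, 2 of 13 rose and 2 fell. Nkx2-2 rose, and so did Gpr17, a receptor of committed precursors, from 0.075 ± 0.0649 to 0.866 ± 0.183 CPM. Bcas1, a marker of early myelinating cells, fell from 78.4 ± 7.2 to 10.2 ± 0.976 CPM. Of 17 astrocyte markers 2 rose and 3 fell, among them Sparcl1, a secreted matricellular protein gene, from 910 ± 399 to 9.44 ± 1.12 CPM. Of 18 neuronal cytoskeleton and RNA-binding markers 3 rose and 2 fell, including Stmn3, which rose from 2.05 ± 1.2 to 30.8 ± 2.19 CPM, and Gap43. Of 14 proneural genes 1 rose and 1 fell (Mfng, -3.81 ± 0.64), and of 20 synaptic genes 2 rose. Of 6 GABAergic genes 2 fell, among them Lhx8, from 2.61 ± 0.399 CPM to 3 reads in all, a ratio of 44.6 with an interval of 15.3 to 216. Of 11 fibroblast and smooth muscle markers 3 rose and 5 fell: the smooth muscle genes Acta2 (from 4.36 ± 2.14 to 579 ± 16.6 CPM) and Tagln rose, and the mesenchymal transcription factor Twist1 and the collagen gene Col6a2 fell. For the proneural, synaptic, GABAergic, fibroblast and chromodomain helicase lists, the median, mean and test differed in sign.

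Of the 19 measured neural stem cell markers, 20 DNA replication genes and 20 mitosis genes, 0 passed in edgeR or limma-voom with all libraries. In edgeR without the 3 libraries, 8 stem cell markers rose and 4 fell, 4 replication genes rose and 11 fell, and 10 mitosis genes rose and 2 fell (medians 0.01, -0.13 and 0.08; camera adjusted p = 0.534, 0.512 and 0.415). At an unadjusted p under 0.05, 4 stem cell markers were higher and 2 lower, and 0 replication and 0 mitosis genes passed, while DESeq2 called 3 stem cell markers higher and 2 lower. It gave p-values for 18 of the stem cell markers, 9 of the replication genes, of which it called 0, and 0 of the mitosis genes. No member passed among the 20 ribosome biogenesis, 15 Notch, 15 growth factor feedback, 20 cholesterol synthesis and 17 glycolysis genes and 13 mitochondrial mRNAs, of which limma-voom called 0 and DESeq2 1 Notch and 1 feedback gene. DESeq2 gave p-values for all of these genes except in the feedback, cholesterol and glycolysis lists, where it did so for 11, 11 and 12. At an unadjusted p under 0.05 these lists held 3, 1, 2, 2, 1 and 0 genes. In the other 9 libraries 16 cholesterol genes fell and 0 rose (median -0.27; camera adjusted p = 0.000712, and adjusted p = 0.079 with an estimated correlation). Likewise 9 Notch genes fell and 2 rose (camera adjusted p = 0.0186, and adjusted p = 0.52 with an estimated correlation). The biogenesis, feedback, glycolysis and mitochondrial lists then had 5, 6, 9 and 5 members higher and 8, 5, 6 and 0 lower, and did not pass camera. Single members passed elsewhere. The Wnt target Lef1 (-3.02 ± 0.46) and the imprinted gene Ndn (-2.89 ± 0.28) fell, and the Polycomb subunit gene Phf19 rose (3 ± 0.45). Slc7a11, a cystine transporter gene of the integrated stress response, rose from 15.5 ± 9.43 to 153 ± 11 CPM. Among the other 9 libraries 14 of the 18 genes of that response rose and 3 fell (camera adjusted p = 1.49e-11, and adjusted p = 0.0326 with an estimated correlation).

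The number called at 3 h varied with the libraries, the tool (2023 with DESeq2) and the length offset (719). It was 1636 without 3 h wild-type replicate 1, and 442, 433 and 419 without 3 h replicate 1, 2 or 3 labelled Chd5-/-.

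At 48 h, several oligodendrocyte lineage genes and p53 targets were higher in the libraries labelled Chd5-/-, and the neurogenic gene Insm1 was lower. Gpr17 (ENSMUSG00000052229, chromosome 18, 31942997 to 31949636), a receptor of committed oligodendrocyte precursors, rose from 0.752 ± 0.219 CPM in wild type to 34.5 ± 0.329 CPM (log2 fold change 5.5 ± 0.41, adjusted p = 7.24e-05). Nkx2-2 rose from 0.329 ± 0.0418 to 11.4 ± 2.26 CPM (5.09 ± 0.31, adjusted p = 9.23e-05). Cdkn1a rose from 11.3 ± 3.41 to 124 ± 24.9 CPM (3.46 ± 0.29, adjusted p = 0.000162). Insm1, a transcription factor gene of neurogenic progenitors, fell from 13.2 ± 1.55 to 2.46 ± 0.531 CPM (-2.42 ± 0.38, adjusted p = 0.00745).

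Of 16043 genes, 440 passed, 246 higher and 194 lower, and 427 changed at least 2-fold. With the 3 libraries that stood apart left out 7791 passed (4224 higher and 3567 lower), among them all 440 in the same direction. Among the higher genes, Lnx1 rose from 0.712 ± 0.282 to 34.7 ± 16.8 CPM. The Iroquois factor Irx1 rose from 0.554 ± 0.353 to 18.9 ± 6.09 CPM. Tubg2, Kctd4, Plxdc2 and Ptprt rose by 5.34, 5.16, 4.66 and 4.64 on the log2 scale. Hhip, an antagonist of Hedgehog ligands, was 5.07 ± 1.15 higher (adjusted p = 0.0417). This call was lost without any 1 of 9 libraries (adjusted p up to 0.178, without wild-type replicate 1 at 48 h, and from 4.86e-05 to 0.2 over all alternatives). Among the lower genes, Edil3 had 55 ± 26.6 CPM in wild type and 0 reads in the libraries labelled Chd5-/-, at least 862-fold lower. The wild-type excess of Zcchc12, Fgl2, Pitpnm1, Minar2 and Nynrin was 1870, 344, 242, 217 and 180 (intervals 519 to 15500, 61.8 to 13600, 82.9 to 1170, 60.2 to 1800 and 49.9 to 1490). Hdac11 fell from 32.5 ± 2.69 to 0.129 ± 0.126 CPM and Ctsz from 19.4 ± 11.2 to 0.154 ± 0.216 CPM. Tpbg, which encodes a Wnt-inhibitory membrane protein, fell from 20.8 ± 4.01 to 0.15 ± 0.0435 CPM, and the protocadherin Pcdhgb5 from 117 ± 5.22 to 0.559 ± 0.343 CPM.

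Of 13 oligodendrocyte lineage markers, 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 1.29), and camera gave an adjusted p of 6.63e-07, with adjusted p = 0.00675 with an estimated correlation. Beside Gpr17 and Nkx2-2, Pdgfra, the receptor gene of oligodendrocyte precursors, rose from 7.11 ± 1.9 to 42 ± 18 CPM (adjusted p = 0.0301). This call was lost in 8 of the fits with 1 library left out (adjusted p up to 0.117, without replicate 3 labelled Chd5-/- at 48 h, and from 9.5e-10 to 0.12 over all alternatives). Bcas1 again fell, from 127 ± 22.4 to 16.4 ± 5.45 CPM. Among the other 9 libraries 8 members rose and 4 fell, and the camera adjusted p was 0.116. Of the 17 genes of the p53 list 3 rose (7 adjusted over the list alone; median 0.85), and camera gave an adjusted p of 1.88e-07, with adjusted p = 0.00675 with an estimated correlation. These were Cdkn1a, Ccng1 (from 21.3 ± 12.3 to 112 ± 11.5 CPM) and Phlda3 (from 6.45 ± 1.62 to 34 ± 4.78 CPM). The calls of Ccng1 and Phlda3 were lost in 4 and 5 of the fits with 1 library left out. Their adjusted p rose to 0.0807 without replicate 3 labelled Chd5-/- and 0.0689 without wild-type replicate 1 at 48 h, and ran from 3.44e-12 to 0.121 and 1.06e-09 to 0.0689 over all alternatives. Among the other 9 libraries 15 members of the p53 list rose and 2 fell, with a camera adjusted p of 1.44e-09.

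Of 10 Hox genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.77; camera adjusted p = 0.000932, and adjusted p = 0.0468 with an estimated correlation). Hoxd4 had 2.59 ± 1.14 CPM in the libraries labelled Chd5-/- against 0.0582 ± 0.0569 CPM, a call lost without wild-type replicate 1 at 48 h (adjusted p = 0.0509, and from 4.38e-06 to 0.0509 over all alternatives). Among the other 9 libraries the Hox list had 6 members higher and 3 lower and a camera adjusted p of 0.949. Of 10 midbrain and hindbrain factors, 2 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.68, and 0.68 with En1 at its bound; camera adjusted p = 0.000526, and adjusted p = 0.494 with an estimated correlation). Irx1 and Lmx1b rose (Lmx1b from 3.23 ± 1.04 to 12.7 ± 0.856 CPM), and En1, of the midbrain and hindbrain boundary, was at least 19.8-fold lower, from 1.27 ± 0.279 CPM to 0 reads. In the other 9 libraries 7 of these factors rose and 1 fell (camera adjusted p = 0.021, and adjusted p = 0.405 with an estimated correlation). Of the 14 proneural genes 1 fell, Insm1 (2 adjusted over the list alone; median -0.56; camera adjusted p = 0.0111, and adjusted p = 0.494 with an estimated correlation). With the 3 libraries left out 11 fell and 2 rose (camera adjusted p = 0.00092, and adjusted p = 0.0937 with an estimated correlation).

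The 22 interferon response genes were higher as a set (2 rose, 12 adjusted over the list alone; median 2.12; camera adjusted p = 3.79e-06, and adjusted p = 0.935 with an estimated correlation). This set moved with 1 library: its mean log2(CPM + 1) was 5.6 in replicate 2 labelled Chd5-/- and 2.75 and 2.73 in replicates 1 and 3, and without the 3 libraries its median was 0.23 (9 rose and 4 fell; camera adjusted p = 0.315). Elsewhere, Sfrp1, a secreted Wnt inhibitor, rose from 0.325 ± 0.147 to 6.19 ± 1.27 CPM, and Tek, an endothelial receptor gene, fell from 6.98 ± 0.547 to 0.363 ± 0.152 CPM. Of the 19 stem cell markers, 20 replication and 20 mitosis genes, 0 passed in edgeR or limma-voom with all libraries. In edgeR without the 3 libraries, 7 stem cell markers rose and 10 fell, 7 replication genes rose and 4 fell, and 4 mitosis genes rose and 3 fell (medians -0.21, 0.04 and 0.07; camera adjusted p = 0.949, 0.949 and 0.995). In that fit astrocyte markers were higher (13 rose and 4 fell; camera adjusted p = 0.00105) and cholesterol genes lower (14 fell and 0 rose; camera adjusted p = 7.12e-05), with adjusted p = 0.113 and 0.0685 with an estimated correlation. Ribosome biogenesis genes passed as higher (14 rose and 3 fell; camera adjusted p = 0.0472), and glycolysis genes (4 rose and 8 fell; 0.0472) and Wnt genes (6 rose and 11 fell; 0.0446) as lower. With an estimated correlation their adjusted p was 0.473, 0.301 and 0.227. At an unadjusted p under 0.05 with all libraries, 2 stem cell markers were higher and 4 lower and 0 cell cycle genes passed, and DESeq2 called 1 stem cell marker higher and 2 lower. DESeq2 gave p-values for 18 stem cell markers, 9 replication genes, of which it called 0, and 0 mitosis genes. For the synaptic, GABAergic, ribosomal, forebrain, glycolysis and imprinted lists, the median, mean and test differed in sign.

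Fewer genes passed at 48 h with only the 6 libraries of that time (263) and without replicate 1 or 3 of either genotype at 48 h (197 and 200 for wild type, 210 and 184 for the other label). With an offset for transcript length 267 passed, and Ptprt was lost at an adjusted p of 0.16 (over all alternatives 4.34e-18 to 0.16). More passed with DESeq2 (872), without wild-type replicate 1 at 3 h (1454) and with a replicate block within the 48 h libraries (1330), a fit added after the data were seen.

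Of the 1077 genes called at 3 h and the 440 at 48 h, 256 passed at both times, and 251 of them in the same direction: 144 higher and 107 lower in the libraries labelled Chd5-/-, where independent lists of these sizes would share 8 and 6.7. Nkx2-2, Ddit4l, Irx1 and Cdkn1a were among the shared higher genes, and Edil3, Zcchc12, Hdac11 and Bcas1 among the shared lower genes. A further 821 genes passed at 3 h alone and 184 at 48 h alone, which does not show that they differed between the times. Fisher's exact test gave p = 2.68e-190 as a description, since genes are not independent, and the fold changes of the genes called at 3 h correlated across genes with r = 0.787, against r = 0.442 over all genes. Without the 3 libraries that stood apart 5144 genes passed at both times, 3885 in the same and 1259 in the opposite direction, where independent lists would share 1150.5 higher and 901.6 lower. The correlation for genes called at 3 h was then r = 0.593. The groups at the 2 times share no libraries, though the labels do not say whether they share cultures.

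**Figure D3:**
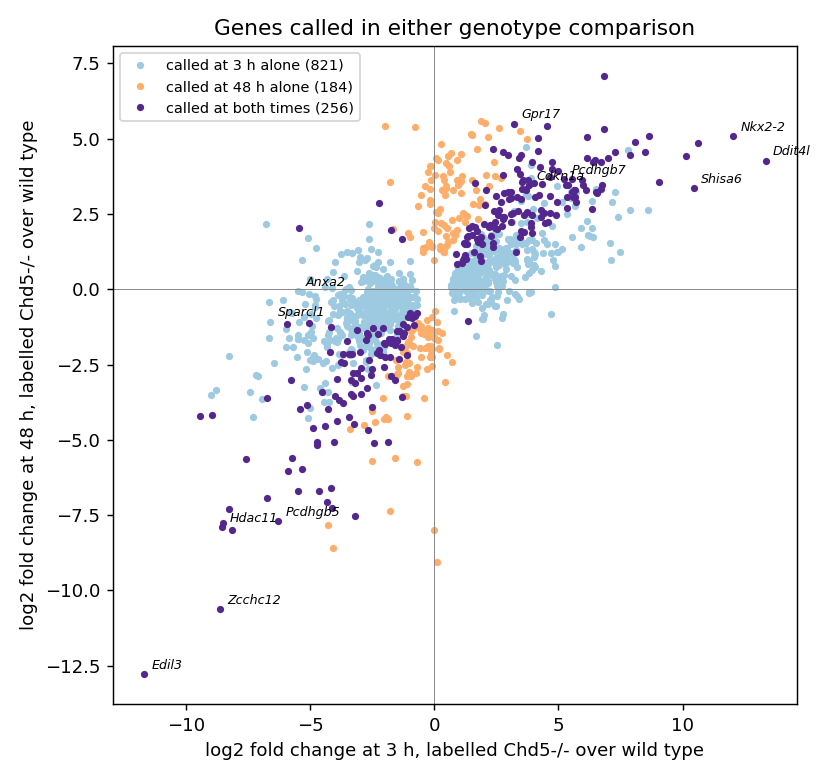
Log2 fold change, labelled Chd5-/- over wild type, at 3 h (horizontal axis) and 48 h (vertical axis), for genes called at either time; each point is a gene. The 256 genes called at both times have the same direction at both, except 5 of opposite direction.

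Between 3 h and 48 h in wild type, several astrocyte and Notch pathway genes rose and several genes of ribosome production and sterol synthesis fell. Slc1a2, the astrocyte glutamate transporter gene, rose from 12.4 ± 5.15 to 142 ± 43.6 CPM (log2 fold change 3.51 ± 0.41, adjusted p = 0.00116), and Aqp4, the astrocyte water channel gene, from 7.29 ± 4.66 to 72.6 ± 40.4 CPM. Ncl, which encodes nucleolin, fell from 1430 ± 302 to 400 ± 69.8 CPM (-1.84 ± 0.24, adjusted p = 0.00187). Vgf, which encodes a secreted neuropeptide precursor, fell from 33.3 ± 16 to 1.41 ± 0.253 CPM (-4.56 ± 0.41, adjusted p = 0.000435).

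Of 16043 genes 3668 passed, 2044 higher and 1624 lower at 48 h, and 12539 passed without the 3 libraries (6208 higher and 6331 lower). Among the largest rises were the long noncoding RNA Miat (8.6 ± 1.97), the Notch ligand gene Dll4 (6.34 ± 1.11), Dscaml1 (5.74 ± 1.45), Mmd2 (5.12 ± 0.82), the adhesion molecule gene Vcam1 (4.99 ± 0.86), Mybpc1 (4.93 ± 1.4), Hapln3 (4.87 ± 1.2) and Atp13a4 (4.86 ± 0.77). Without wild-type replicate 1 or 3 at 48 h the calls of Dscaml1, Mybpc1 and Hapln3 (adjusted p = 0.0201, 0.0305 and 0.0186) were lost (adjusted p up to 0.0599, 0.0807 and 0.0551). They were also lost with limma-voom, which gave the top of their ranges over all alternatives (4.2e-08 to 0.0895, 5.11e-09 to 0.114 and 3.84e-10 to 0.119). The calls of Dscaml1 and Mybpc1 were also lost without wild-type replicate 2 at 3 h, and that of Mybpc1 without replicate 1 or 3 at 3 h. Among the largest falls were the noncoding RNAs Bc1 (-6.34 ± 0.9) and Snhg9 (-5.51 ± 1.13), Abi3 (-5.23 ± 0.75), Aldh1a3, a retinoic acid synthesis gene (from 29.7 ± 1.58 to 0.969 ± 0.647 CPM), Rhox5, Slamf1 and Stpg4. The call of Stpg4 (adjusted p = 0.0272) was lost without wild-type replicate 1 at 3 h or replicate 1 or 3 at 48 h (adjusted p up to 0.0991, and from 1.08e-08 to 0.0991 over all alternatives). For several of these falls wild-type replicate 1 at 3 h stood above the rest, with SDs near the 3 h means: 66.5 ± 78.3 CPM for Bc1 and 9.01 ± 12.5 CPM for Snhg9. In the fit of the other 9 libraries the falls of Bc1, Snhg9, Abi3 and Slamf1 shrank to -4.63, -3.87, -3.8 and -3.54, while those of Aldh1a3, Rhox5 and Stpg4 were -5.58, -5.58 and -5.36.

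Of 17 astrocyte markers 11 rose and 1 fell (13 and 1 adjusted over the list alone; median 2.03; camera adjusted p = 1.35e-05, and adjusted p = 0.748 with an estimated correlation). Beside Slc1a2 and Aqp4, Fgfr3 rose from 123 ± 33.5 to 500 ± 93.4 CPM and Mlc1 from 548 ± 18.1 to 1380 ± 35.2 CPM. Of 15 Notch genes 7 rose (7 adjusted over the list alone; median 1.16; camera adjusted p = 0.00719, and adjusted p = 0.748 with an estimated correlation), among them Lfng (1.07 ± 0.26). Of 20 ribosome biogenesis genes 8 fell (12 adjusted over the list alone; median -0.92; camera adjusted p = 1.38e-05, and adjusted p = 0.748 with an estimated correlation), such as Ncl, Nop58 and Nolc1. Of 20 cholesterol synthesis genes 4 fell (4 adjusted over the list alone; median -0.52; camera adjusted p = 0.000703, and adjusted p = 0.748 with an estimated correlation). Idi1 fell from 437 ± 108 to 79.2 ± 53.3 CPM, and Pmvk fell as well. Of 63 ribosomal protein genes 16 fell (54 adjusted over the list alone; median -1.62; camera adjusted p = 2.11e-09, and adjusted p = 0.748 with an estimated correlation). This set was high in wild-type replicate 1 at 3 h and had a median of -0.47 without the 3 libraries (56 fell and 2 rose; camera adjusted p = 0.000755, and adjusted p = 0.776 with an estimated correlation). In that fit 12 Notch genes rose and 1 fell and 19 ribosome biogenesis genes fell, and neither list passed with an estimated correlation (adjusted p = 0.123 and 0.0578).

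The cell cycle lists fell in 2 of the 3 wild-type libraries at 48 h. Camera gave the 20 mitosis genes an adjusted p of 2.45e-05 and the 20 replication genes 3.14e-07 (medians -1.9 and -1.9; adjusted p = 0.748 with an estimated correlation for both). Singly, 0 mitosis genes and 3 replication genes passed in edgeR (0 and 6 adjusted over the list alone). Of the mitosis genes 2 were lower at an unadjusted p under 0.05, and 8 passed in limma-voom; DESeq2 gave a p-value for 0 of the 20. Their levels moved with replicate 2: mean log2(CPM + 1) of the mitosis genes was 3.34 in replicates 1 and 3 and 7.13 in replicate 2, near the 7.21 to 7.86 of the 3 h libraries. Replicate 2 likewise kept cholesterol synthesis genes high (8.33 against 6.09 and 6.08) and astrocyte markers low (5.83 against 7.61 and 7.62). Without the 3 libraries all 20 mitosis, 20 replication and 20 cholesterol genes fell (medians -4.56, -3.65 and -2.08). Their camera calls then held with an estimated correlation (adjusted p = 0.000552 for each), as did that of the astrocyte markers (adjusted p = 0.000901 with an estimated correlation). Replicate 2 stood apart in these same lists, so a fit without it is no separate support for them.

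**Figure D4:**
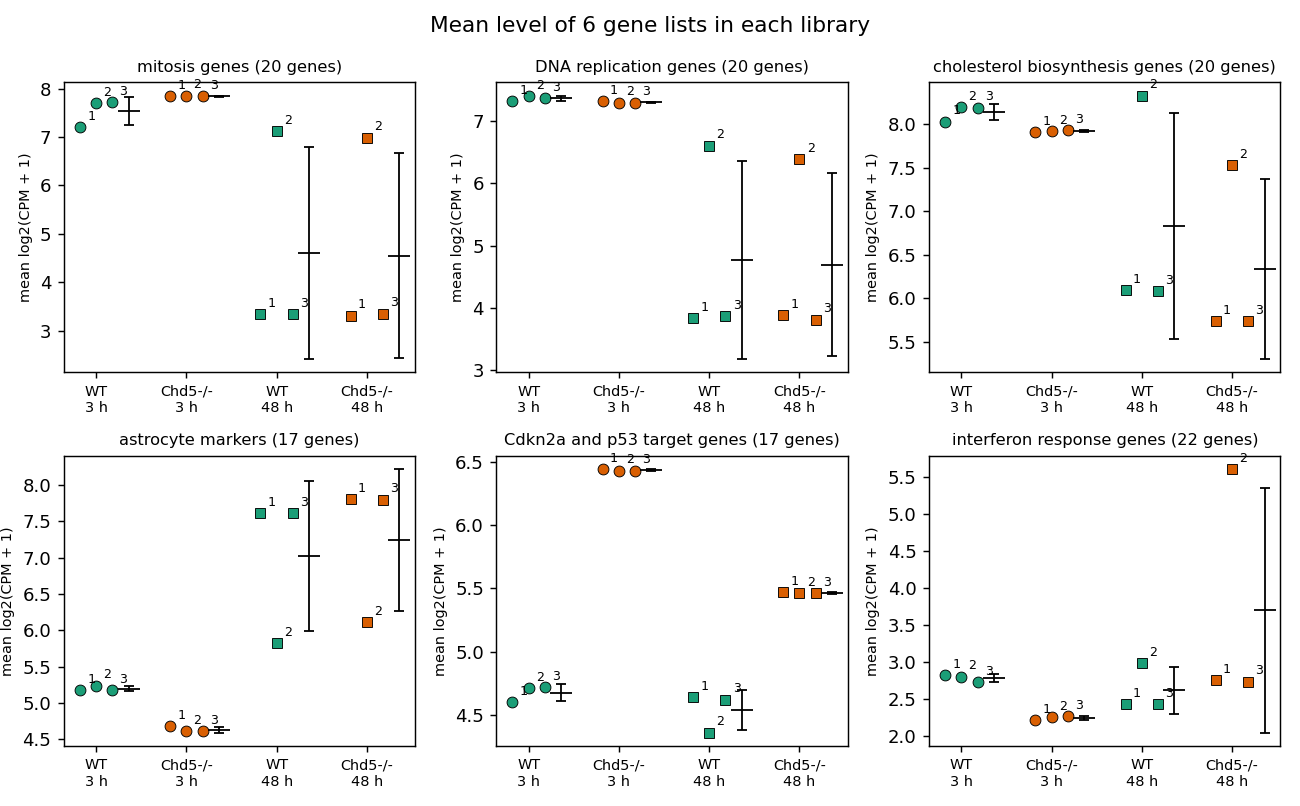
Mean log2(CPM + 1) of 6 gene lists (vertical axes) in each library, by genotype label and time; numbers give the replicate and the bar to the right of each group the mean with SD. In the mitosis panel replicate 2 lies at 7.13 and 6.99 at 48 h and the other 48 h libraries between 3.31 and 3.35.

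In other lists of wild type, the receptor gene Egfr (1.52 ± 0.3) and the glutamate transporter gene Slc1a3 of the stem cell list rose. The neuronal vesicle gene Nsg2 rose from 30.6 ± 4.36 to 270 ± 148 CPM, and Gad1, which encodes the synthetic enzyme of GABA, from 5.52 ± 1.19 to 31 ± 1.38 CPM. The synaptic genes Nlgn1, Stx1a and Syn2 rose as well. Of the oligodendrocyte lineage list 6 rose and 1 fell, among them Pdgfra (2.43 ± 0.56) and Nkx2-2 (at least 4.99-fold), with a median of 1.06 with Nkx2-2 at its bound and a camera adjusted p of 0.0655. Cdkn1a fell (-2.13 ± 0.28). Of 19 chromodomain helicase and NuRD genes 2 rose, among them Chd3 (1.04 ± 0.2), and 2 fell. Of 17 Polycomb and H3K27 demethylase genes 3 rose, Cbx7 (2.15 ± 0.28), Ezh1 (1.76 ± 0.24) and Kdm6b (1.68 ± 0.25), and 0 fell. Without the 3 libraries 6 and 7 members of these lists rose and 11 and 9 fell (medians -0.21 and -0.42). In that fit the stress response list passed as lower (14 fell and 1 rose; camera adjusted p = 5.72e-07, and adjusted p = 0.0387 with an estimated correlation). The growth factor feedback, glycolysis and mitochondrial lists also passed as lower (10, 13 and 13 fell and 4, 3 and 0 rose; camera adjusted p = 0.000105, 0.00209 and 0.000139). The proneural, neuronal cytoskeleton, oligodendrocyte and Wnt lists passed as higher (12, 11, 9 and 10 rose and 4, 7, 3 and 5 fell; camera adjusted p = 0.0112, 0.0144, 0.00513 and 0.0112). None of these 7 passed with an estimated correlation (adjusted p = 0.272 for the mitochondrial list and 0.0876 for the others).

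With only the 6 wild-type libraries 0 genes passed in edgeR (3649 at an unadjusted p under 0.05), while with all 12 libraries 4876 passed in DESeq2 and 3348 in limma-voom. The count was 1464 and 1472 without wild-type replicate 1 or 3 at 48 h, and 5419 without wild-type replicate 1 at 3 h.

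Between 3 h and 48 h in the libraries labelled Chd5-/-, most astrocyte markers and several oligodendrocyte genes rose and several p53 targets fell. Sparcl1, of the astrocyte list, rose from 9.44 ± 1.12 to 1220 ± 499 CPM (log2 fold change 7.02 ± 0.54, adjusted p = 7.6e-05). Pdgfra rose from 1.39 ± 0.0582 to 42 ± 18 CPM (4.91 ± 0.61, adjusted p = 0.000685). Cdkn1a fell from 695 ± 11.8 to 124 ± 24.9 CPM (-2.48 ± 0.28, adjusted p = 0.000425), and the smooth muscle actin gene Acta2 from 579 ± 16.6 to 5.91 ± 4.02 CPM.

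Of 16043 genes 3544 passed, 2255 higher and 1289 lower at 48 h, and 13029 passed without the 3 libraries (6413 higher and 6616 lower). Olfml1 and Ott had 0 reads at 3 h and were at least 132-fold and 92.5-fold higher, and Mroh7, Dscaml1 and Nkain2 had ratios of 347, 320 and 205 (intervals 96.1 to 2870, 110 to 1550 and 70.3 to 996). Dhrs3 and Pcdha8 were at least 129-fold and 88.7-fold higher (adjusted p = 0.0161 and 0.0178). Both calls were lost without replicate 1, 2 or 3 labelled Chd5-/- at 3 h (adjusted p up to 0.0533 and 0.0563; over all alternatives 1.52e-09 to 0.0796 and 5.71e-06 to 0.0563), and that of Pcdha8 also without replicate 1 or 3 at 48 h. Beside Acta2, the activity-dependent transcription factor Npas4 fell from 69 ± 2.13 to 0.796 ± 0.607 CPM, and Nrgn, Kcnmb1, Spp1 and Tmem182 fell by 4.99, 4.95, 4.8 and 4.44. Tnfsf18 also fell (adjusted p = 0.0141), a call lost without replicate 1 or 3 labelled Chd5-/- at 48 h (adjusted p up to 0.0577, and from 7.66e-13 to 0.0577 over all alternatives).

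Of 17 astrocyte markers 13 rose (15 adjusted over the list alone; median 2.74; camera adjusted p = 3.34e-08, and adjusted p = 0.634 with an estimated correlation). The gap junction gene Gja1 (from 3.8 ± 0.646 to 118 ± 72 CPM) and Fgfr3 were among them. Of 13 oligodendrocyte lineage markers 5 rose and 1 fell (9 and 1 adjusted over the list alone; median 1.39; camera adjusted p = 0.00114, and adjusted p = 0.0855 with an estimated correlation). Gpr17 (5.31 ± 0.4) and the proteoglycan gene Cspg4 (2.74 ± 0.47) were among those that rose. Of the 17 genes of the p53 list 7 fell (9 adjusted over the list alone; median -1.02; camera adjusted p = 0.000396, and adjusted p = 0.0855 with an estimated correlation), including Pmaip1 (-2.38 ± 0.43) and Aen (-1.14 ± 0.26). Of 15 Notch genes 5 rose (median 0.7; camera adjusted p = 0.0347, and adjusted p = 0.719 with an estimated correlation), with Hes5 from 3.25 ± 0.346 to 106 ± 50.1 CPM and Hey1 (2.44 ± 0.51). Of 13 mitochondrial mRNAs 9 fell (9 adjusted over the list alone; median -1.37; camera adjusted p = 1.53e-05, and adjusted p = 0.634 with an estimated correlation), among them mt-Co3 from 3720 ± 94.4 to 904 ± 132 CPM. In the fit of the other 9 libraries the astrocyte and p53 lists passed with an estimated correlation (adjusted p = 0.00247 and 0.0329), and the oligodendrocyte, Notch and mitochondrial lists did not (adjusted p = 0.0759, 0.166 and 0.227).

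Ribosome biogenesis genes fell in 6 of 20 cases (6 adjusted over the list alone; median -0.62; camera adjusted p = 0.000976, and adjusted p = 0.719 with an estimated correlation), again with Ncl (-1.84 ± 0.24) and Nop58 (-2.29 ± 0.31). The mitosis, replication and cholesterol lists moved with replicate 2 here too. Of the 20 members each, 0, 4 and 2 fell with all libraries (medians -2.35, -2.1 and -1.34; camera adjusted p = 2.06e-05, 2.79e-06 and 0.000202, and adjusted p = 0.719 with an estimated correlation for each). For the mitosis genes, 3 reached an unadjusted p under 0.05 and 12 passed in limma-voom; DESeq2 gave a p-value for 0 of the 20. Without the 3 libraries all 20 of each fell, with adjusted p = 0.000283, 0.00247 and 0.000886 with an estimated correlation. The 18 integrated stress response genes were lower as a set (median -0.58; camera adjusted p = 0.0355, and adjusted p = 0.873 with an estimated correlation). Singly, 0 passed in edgeR, 4 reached an unadjusted p under 0.05, and 4 passed in limma-voom and 3 of the 9 with a p-value in DESeq2. Replicate 2 held them at a mean log2(CPM + 1) of 7.24 against 4.84 and 4.78, and in the other 9 libraries 17 fell and 1 rose (median -1.91; camera adjusted p = 5.88e-13, and adjusted p = 0.00864 with an estimated correlation). Of 22 interferon genes 11 rose (16 adjusted over the list alone; median 2.52; camera adjusted p = 0.00114, and adjusted p = 0.824 with an estimated correlation). Irf7 went from 0.117 ± 0.056 to 22.6 ± 33.7 CPM. The mean of the list in replicate 2 was 5.6 against 2.75 and 2.73, and the median without the 3 libraries was 0.61 (12 rose and 2 fell; camera adjusted p = 0.325).

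Of the 14 proneural genes 3 rose and 3 fell (camera adjusted p = 0.691). Insm1 (-3.3 ± 0.39) and Sox11 (-1.27 ± 0.24) were among those that fell and the Notch ligand gene Dll3 (3.2 ± 0.53) among those that rose. Nes, which encodes the progenitor intermediate filament nestin, fell from 1170 ± 36.3 to 445 ± 107 CPM, and Sox9, a glial transcription factor, rose from 56.1 ± 3.86 to 174 ± 13.2 CPM. Gad1 rose from 1.8 ± 0.247 to 29.3 ± 13.2 CPM. In the other 9 libraries the feedback, glycolysis and ribosomal protein lists passed as lower (11, 13 and 47 fell and 3, 2 and 2 rose; camera adjusted p = 4.14e-05, 5.58e-05 and 0.0374) and the Wnt list as higher (13 rose and 5 fell; 0.029). With an estimated correlation their adjusted p was 0.0759, 0.0719, 0.745 and 0.166.

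With only the 6 libraries labelled Chd5-/- 7836 genes passed, and without wild-type replicate 1 at 3 h 7280. Without replicate 1, 2 or 3 labelled Chd5-/- at 3 h the count was 1708, 1745 and 1740, and without replicate 1 or 3 at 48 h 1803 and 1807.

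The change between the times differed between genotypes for 37 genes, 22 with a larger and 15 with a smaller value in the libraries labelled Chd5-/-. Several genes low at 3 h in the libraries labelled Chd5-/- lay near or above wild type by 48 h. Anxa2, which encodes a membrane-binding annexin, lay 5.48 below wild type on the log2 scale at 3 h and 0.07 below it at 48 h (interaction 5.41 ± 0.54, adjusted p = 0.00248). Conversely, Ddit4l and Nkx2-2, switched on in the libraries labelled Chd5-/- at 3 h, lay closer to wild type at 48 h. All of these directions are of the label, since the level of Chd5 does not show a loss.

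All 37 changed at least 2-fold. Without the 3 libraries that stood apart 6669 passed (3187 higher and 3482 lower), among them all 37 in the same direction. Twist1 (ENSMUSG00000035799) went from 5.43 below wild type to 2.02 above it (interaction 7.45 ± 0.74, adjusted p = 0.00248). Sparcl1 (ENSMUSG00000029309) went from 6.59 below to 1.08 below (5.51 ± 0.62). Sirt6, which encodes a chromatin deacylase, went from 6.66 below to 1.62 below (5.04 ± 0.61), and the microtubule-associated Eml2 from 4 below to 0.91 above (4.91 ± 0.56). Col5a2, a fibrillar collagen gene, lay 2.23 below at 3 h and 2.88 above at 48 h (5.11 ± 0.61). The difference shrank from 13.34 to 4.27 for Ddit4l (-9.07 ± 0.84, adjusted p = 0.00199) and from 12.04 to 5.09 for Nkx2-2 (-6.95 ± 0.67, adjusted p = 0.00476). At 3 h wild type had 1 Ddit4l and 0 Nkx2-2 reads and the other label 2 Twist1 reads (wild-type excess 51.2, interval 14.2 to 423). Their fitted values are no bounds.

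Calls of 5 further genes were lost in most fits with 1 library left out: Shisa6 (-7.08 ± 1.14, adjusted p = 0.0365), Rin3 (-5.52 ± 0.76, 0.015), Ank3 (-3.94 ± 0.63, 0.0364), Insm1 (-3.13 ± 0.52, 0.0418) and Ndn (2.36 ± 0.37, 0.033). Insm1 lay 0.72 above wild type at 3 h and 2.42 below it at 48 h. The 5 calls were lost in 9, 8, 9, 10 and 9 of the 12 fits with 1 library left out, with adjusted p up to 0.159, 0.0777, 0.136, 0.157 and 0.136. The highest came without wild-type replicate 1 at 48 h for Shisa6 and Ank3, without replicate 1 labelled Chd5-/- at 48 h for Rin3, and without replicates 3 and 2 labelled Chd5-/- at 3 h for Insm1 and Ndn. Over all alternatives the adjusted p ran from 3.37e-06 to 0.226, 4.44e-07 to 0.246, 8.23e-06 to 0.226, 3.62e-08 to 0.246 and 1.35e-08 to 0.255.

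Among the lists, astrocyte markers were higher (1 of 17 rose, Sparcl1; median 0.69; camera adjusted p = 0.0403, and adjusted p = 0.746 with an estimated correlation). The p53 list was lower (median -0.97; camera adjusted p = 0.00123, and adjusted p = 0.118 with an estimated correlation), with 0 passing in edgeR or limma-voom. DESeq2 called 2, and 2 fell adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher and 6 lower. In the other 9 libraries 9 astrocyte markers rose and 5 fell, with the median down to 0.15, and 3 genes of the p53 list rose and 14 fell (median -1.21). Both lists passed camera there (adjusted p = 0.0188 and 0.0299 with an estimated correlation). Interferon genes were higher as a set (median 3.47; camera adjusted p = 3.81e-09, and adjusted p = 0.746 with an estimated correlation). Singly, 0 passed in edgeR or limma-voom and 1 of the 11 with a p-value in DESeq2, with 14 higher at an unadjusted p under 0.05 and 11 adjusted over the list alone. Ribosomal protein genes were higher (median 1.43; camera adjusted p = 5.75e-09, and adjusted p = 0.746 with an estimated correlation) and mitochondrial mRNAs lower (median -1.03; camera adjusted p = 0.00114, and adjusted p = 0.746 with an estimated correlation). Of both lists, 0 passed in edgeR, DESeq2 and limma-voom, with 5 and 1 at an unadjusted p under 0.05 in edgeR; DESeq2 gave p-values for 30 of the 63 ribosomal genes. The interferon set was highest in replicate 2 labelled Chd5-/- at 48 h, but in the other 9 libraries 15 of 20 members were still higher and 0 lower (median 1.17; camera adjusted p = 0.000363, and adjusted p = 0.0619 with an estimated correlation). The ribosomal set moved with wild-type replicate 1 at 3 h, in which mitochondrial genes were also low. In the other 9 libraries the medians of these lists were 0.11 and -0.27 (16 rose and 3 fell, and 0 rose and 7 fell; camera adjusted p = 0.0563 and 0.0524). In that fit the proneural, neuronal cytoskeleton, stress response and glycolysis lists passed as lower (camera adjusted p = 0.0158, 0.000324, 0.000131 and 0.0158). The immediate early and ribosome biogenesis lists passed as higher (0.000175 and 0.026). None of these 6 passed with an estimated correlation (adjusted p = 0.129, 0.0619, 0.0782, 0.179, 0.0952 and 0.49).

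The count of 37 became 310 without wild-type replicate 1 at 3 h, 108 and 99 without replicate 2 of wild type or of the other label at 48 h, between 15 and 20 without any 1 of the other 9 libraries, and 349 with DESeq2. It was 18 with the replicate-number block, 25 with the length offset.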

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

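The tests of the 3 libraries that stood apart were all chosen after the results were seen; the interaction and its splits were planned.

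The effect of the genotype label differed between 3 h and 48 h for 37 genes by the interaction test. The log2 difference, with the 48 h effect less the 3 h effect, was 7.45 for Twist1, 5.51 for Sparcl1, 5.41 for Anxa2, 5.11 for Col5a2, 5.04 for Sirt6, 4.91 for Eml2 and 2.36 for Ndn. It was -3.13 for Insm1, -3.94 for Ank3, -5.52 for Rin3, -6.95 for Nkx2-2, -7.08 for Shisa6 and -9.07 for Ddit4l. For Ndn, Insm1, Ank3, Rin3 and Shisa6 the adjusted p rose to 0.136, 0.157, 0.136, 0.0777 and 0.159 with 1 library left out, and ran over all alternatives from 1.35e-08 to 0.255, 3.62e-08 to 0.246, 8.23e-06 to 0.226, 4.44e-07 to 0.246 and 3.37e-06 to 0.226. Of the lists, the test of the difference gave camera adjusted p = 0.0403 for astrocyte markers, 0.00123 for the p53 list, 5.75e-09 for ribosomal protein genes, 3.81e-09 for interferon genes and 0.00114 for mitochondrial mRNAs, and none of the 5 passed with an estimated correlation (adjusted p = 0.746, 0.118, 0.746, 0.746 and 0.746). In 60 splits drawn from 200 that kept the times whole, 5 gave at least 37 genes, the real one included, so chance is not excluded for this count. The 4 others kept the genotype groups of 3 h whole and regrouped the 48 h libraries. The 2 highest (356 and 230 genes) set the 3 h libraries labelled Chd5-/- with 2 wild-type libraries of 48 h, so the genotype difference itself entered as an interaction. Such counts point to a structure of the samples, and these splits are no clean measure of chance.

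Wild-type replicate 1 at 3 h stood apart in ribosomal protein genes, in mitochondrial mRNAs and across many genes. Its log2 ratio to replicates 2 and 3 fell with transcript length across 14124 genes (Spearman -0.528, slope -0.624 per doubling of length), while the slopes of the 48 h libraries and of the 3 h libraries labelled Chd5-/- lay between -0.053 and 0.03. A Spearman of -0.377 was also found in replicate 1 labelled Chd5-/- at 3 h, with a slope of only -0.043. On an axis from wild type (0%) to Chd5-/- (100%) of 1615 genes its median position was -3.3%, which argues against a library of the other genotype. Of 5 lists of other cell types the ependymal one was highest (median log2 ratio 1.4 over 7 measured genes), which met the bound set for cells of another type. It fell to 0.59 over 4 genes when set against genes of like length, a check added afterwards; with so few genes, mixed-in cells and the length trend cannot be told apart. A library that favours short transcripts, for example from more broken RNA, may explain its distance, and no biological explanation beyond these was tested.

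At 48 h, replicate 2 of both genotypes kept cell cycle and cholesterol genes near their 3 h level and had lower astrocyte markers than its partners. For 3 h RNA under a wrong label, the lowest chi-square per gene against a 3 h library of the genotype was 151.5. Pairs within a group were compared at a higher read cutoff. Like libraries there gave 1.82 to 5.99, but wild-type replicate 1 at 3 h gave 492.42 and 513.71. The value of 151.5 alone thus does not exclude 3 h RNA. Against their own 48 h partners these libraries gave 255.54 and 265.31 in wild type and 157.18 and 155.65 in the other label. Transcript length did not set them apart (Spearman -0.091 in the library farther from 0). A mixture of 3 h and 48 h RNA would keep each gene between the levels of the other libraries: 3.09% of 10926 genes in the library labelled Chd5-/- and 4.59% of 11203 in wild type lay over 2-fold outside that range (206 above and 132 below; 383 above and 131 below). Of these, 90 lay outside in the same direction in both libraries, where independent sets would share 6.6. The mean log2(CPM + 1) of the 17 glycolysis and hypoxia genes was 7.38 in wild type and 7.36 in the other library, above the 6.31 to 6.44 of the 3 h libraries and the 5.28 to 5.62 of the other 48 h libraries. That of the interferon genes was 5.6 in replicate 2 labelled Chd5-/-, against at most 2.75 in the other libraries of that label. These values argue against a mixture of 3 h and 48 h RNA as the whole cause. A mixture as part of the cause, and cultures in another state that differentiated less far, stay open and untested. The shared number may mark a shared culture day, which the labels do not give.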

How the results depend on the processing

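The fits without the 3 libraries that stood apart and the replicate block within the 48 h libraries were chosen after the data were seen; all other alternatives were planned. Where no cause is given, the cause was not tested.

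The number of genes called stayed within 1.5 times its value with RLE size factors, without a filter on low counts, with a stricter filter and with limma-voom in all 5 comparisons. With RLE size factors, 1054 of the 1077 calls at 3 h and 429 of the 440 at 48 h were kept. DESeq2 gave 2023 genes at 3 h, 872 at 48 h and 349 for the interaction, against 1077, 440 and 37. It gave p-values for 31169 genes, among them 1064, 439 and 37 of these calls but 0 of the 20 mitosis genes and 9 of the 20 replication genes, and its interaction values had a median of 0.137 over all genes against -0.029 in edgeR. With the length offset 719 passed at 3 h (670 of 1077 kept), 267 at 48 h and 25 for the interaction. With only the libraries compared 263 passed at 48 h. Between times 0 then passed in wild type (edgeR, 3649 at an unadjusted p under 0.05) and 7836 under the other label. The spread then rested on 6 libraries, 1 or 2 of them apart. With the number as a replicate block 18 passed for the interaction and 3 with a block of genotype and number. The latter gave 777 between times in wild type and 1914 under the other label. The replicate block within 48 h gave 1330.

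With 1 library left out, the count ran from 419 to 1636 at 3 h, 184 to 1454 at 48 h, 1464 to 5419 and 1708 to 7280 between times in wild type and in the libraries labelled Chd5-/-, and 15 to 310 for the interaction. The highest came without wild-type replicate 1 at 3 h in each comparison. The lowest came without replicate 3 labelled Chd5-/- at 3 h, replicate 3 labelled Chd5-/- at 48 h, wild-type replicate 1 at 48 h, and replicate 1 labelled Chd5-/- at 3 h; for the interaction, without replicate 1 or 3 labelled Chd5-/- at 3 h or replicate 3 at 48 h. With the 3 libraries left out 8659, 7791, 12539, 13029 and 6669 passed, and 3885 instead of 251 passed at both times in the same direction. Groups then held 2 libraries each except the Chd5-/- group of 3 h. Their replicates lay close together (chi-square per gene 1.82 to 5.99), so small differences passed. The labels name no separate cultures, so these may be culture differences.

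Camera called 3, 6, 7, 11 and 5 lists in the 5 comparisons, and 1, 3, 0, 0 and 0 with an estimated correlation, which lets members move together. Fry called 6, 3 and 2 at 3 h, at 48 h and for the interaction. With the 3 libraries left out camera called 7 at 3 h, 15 between times in wild type and 9 for the interaction; with an estimated correlation as well, 2, 1, 5, 6 and 2 in the 5 comparisons.

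Chd5 turned in direction with the length offset, to -0.25 at 3 h and 2.44 at 48 h. The odds ratio near Chd5 at 3 h turned from 1.29 to 0.92 without the 3 libraries. Kdm5d at 3 h (-0.11) turned to 0.02 without a filter, 0.34 in limma-voom, 0.06 with the number as a replicate block, 0.96 without the 3 libraries, and ran from -0.5 (without wild-type replicate 3 at 3 h) to 0.96 (without wild-type replicate 1 at 3 h) with 1 library left out. At 48 h (-0.2) Kdm5d turned to 0.23 without the 3 libraries and ran from -0.35 (without replicate 1 labelled Chd5-/- at 48 h) to 0.05 (without replicate 2) with 1 library left out. The Kdm5d interaction (-0.09) turned to 0.01 with the length offset, 0.22 and 0.3 without wild-type replicates 2 and 3 at 3 h, and 0.05 and 0.14 without replicate 2 of wild type and of the other label at 48 h; its lowest value, -1.15, came without wild-type replicate 1 at 3 h. Xist between times in wild type (0.96) turned to -0.06 without the 3 libraries.

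Of 350 results on named genes, 347 kept their direction and side of the threshold with RLE size factors, 324 without a filter, 321 with limma-voom, 295 with the length offset and 329 with the number as a replicate block; 338 of 340 did with the stricter filter and 340 of 341 with DESeq2. With only the libraries compared 208 of 317 did, and with the block of genotype and number 128 of 219. Of 4200 fits of a named result with 1 library left out, 3573 kept both, 618 lost the call, 3 gained it and 6 turned. Among the other 9 libraries 340 of 350 kept both and 6 gained the call.

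Depth limits what is given for weak genes: with 14.11 M reads or more per library, a gene absent from 3 libraries is bounded near 0.066 CPM. The spread of the 3 libraries limits the rest. In data simulated gene by gene at these depths, 48% of 4-fold and 0% of 2-fold changes were found with all libraries. Without the 3, 100% of both were found.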

Other observations

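The label exchange and the comparison of lines were chosen after the results were seen. The tests of protocadherins and of a second p53 list were set before their values were seen, though prompted by single genes and by the first list.

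Further lists at 3 h held few calls with all 12 libraries, and more members of each passed in the other 9. There 3 immediate early genes rose and 11 fell (camera adjusted p = 0.0282, and adjusted p = 0.333 with an estimated correlation). Of 15 immediate early genes 1 rose and 2 fell; Ier3 had 2 reads in wild type and rose 155-fold (interval 43 to 1280) to 6.84 ± 0.505 CPM. Of 19 chromodomain helicase and NuRD genes 1 fell, of 17 Polycomb genes 1 rose, of 21 Wnt genes 2 fell, of 22 interferon genes 1 rose, of 18 integrated stress response genes 2 rose, and of 13 imprinted genes 1 rose and 1 fell. Of markers of other cell types, 1 of 6 endothelial and 1 of 7 ependymal genes fell and 1 of 5 pluripotency genes rose. In edgeR 0 of 5 neural crest and 0 of 2 microglia genes passed (2 and 1 at an unadjusted p under 0.05; 0 in limma-voom, and 0 of the 4 and 2 with a p-value in DESeq2). Xist had 698 ± 425, 976 ± 83.8, 1350 ± 731 and 496 ± 92.5 CPM in wild type and Chd5-/- at 3 h and then at 48 h. In the same order the Y-linked Kdm5d had 1.41 ± 1.33, 1.26 ± 0.131, 2.11 ± 0.392 and 1.84 ± 0.609 CPM. Of the 5 sex-linked genes of the list 2 were measured, and the Y-linked Ddx3y, Eif2s3y and Uty were not. The low levels of Kdm5d beside Xist thus do not show that a group held cells of both sexes. Neither passed between genotypes (Xist 0.48, adjusted p = 0.598, and -1.45, 0.253; Kdm5d -0.11, 0.925, and -0.2, 1).

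For the counts of called genes, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each of the 4 comparisons 1 split, the real one, reached the count: 1077 genes at 3 h (highest other 2), 440 at 48 h (highest other 2), 3668 between times in wild type (highest other 234) and 3544 between times in the libraries labelled Chd5-/- (highest other 0, with edgeR).

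Many genes were on in 1 genotype and close to absent in the other at both times, and 251 genes passed in the same direction at both. A chromosome segment carried along with the deletion would put them near Chd5: 3 of the 251 (1.2%) lay within 10 Mb. Of all 153 tested genes in that window 13 passed at 3 h (8.5% against 6.7% elsewhere, odds ratio 1.29, Fisher's exact p = 0.332) and 6 at 48 h (3.9% against 2.7%, odds ratio 1.45, p = 0.318). Labels exchanged at 1 time would turn the fold changes, which instead correlated with r = 0.787. Lines or animals that differ apart from Chd5 and an effect of the Chd5 deletion cannot be told apart for any genotype call. The labels give no line or animal per library, and the level of Chd5 does not show a loss.

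Clustered protocadherins, each expressed from few alleles per neuron, could differ if the cultures grew from few founder cells. Of 51 measured, 14 passed at 3 h (13 higher and 1 lower; 27.5% against 6.6% of other genes, Fisher's exact p = 4.29e-06) and 8 at 48 h (7 higher and 1 lower; 15.7% against 2.7%, p = 6.8e-05). In the 9 libraries other than those that stood apart, 30 of 53 passed at 3 h (Fisher's exact p = 0.584) and 39 of 53 at 48 h (p = 0.000145). Pcdhgb5 stood at 40.1 ± 33.5 CPM in wild type and 0.507 ± 0.255 CPM in the libraries labelled Chd5-/- at 3 h, where its call (adjusted p = 0.00853) was lost without replicate 2 or 3 labelled Chd5-/- (adjusted p up to 0.0563, and from 1.62e-12 to 0.0858 over all alternatives). Pcdhgb7 stood at 2.23 and 86.9 CPM at 3 h and 4.04 and 51.3 CPM at 48 h, and Pcdhga6 at 0.616 and 34.2 CPM and at 2.56 and 21.2 CPM; both were chosen after their values were seen. Their 48 h calls (adjusted p = 0.0175 and 0.0203) were lost in 4 and 5 of the fits with 1 library left out (up to 0.0933 without wild-type replicate 3 and 0.0939 without wild-type replicate 1 at 48 h; over all alternatives 2.92e-11 to 0.0933 and 1.77e-13 to 0.0939). Members of the alpha and gamma clusters share constant exons, so their reads may be assigned to the wrong one. Few founder cells and an effect of the genotype cannot be told apart, as either would follow the label.

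Higher p53 activity in the libraries labelled Chd5-/- would also raise p53 targets outside the first list. Of 17 measured genes of a second list 5 rose at 3 h, Fas, Ercc5, Trp53cor1, Tnfrsf10b and Gdf15 (7 adjusted over the list alone; median 1.43; camera p = 2.29e-07, and 0.000526 with an estimated correlation, unadjusted since 1 list was tested). At 48 h 1 rose, Trp53cor1 (median 0.57; camera p = 0.00398, and 0.0146 with an estimated correlation). Among the other 9 libraries 13 rose and 3 fell at 3 h and 11 rose and 3 fell at 48 h. Trp53 itself did not pass (-0.33, adjusted p = 0.384, at 3 h and 0.06, adjusted p = 1, at 48 h), and Cdkn2a RNA was not higher at either time (-3.12 and -0.61). Higher p53 activity may thus go with the label, but whether Chd5 or another difference between the cultures lies behind it stays open.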
